A study of Mus musculus with 8 samples.

How the data were processed

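RNA samples of control and starved C2C12 myotubes, 4 per group, were hybridised to Affymetrix mouse expression arrays, 1 array per sample. The groups and the replicate letters A to H were taken from the labels. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. The letters differ between the groups and were not used to pair arrays.

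The deposited table holds 1 signal per probe set and array as an intensity on a linear scale; how the authors computed these intensities from the scans, and with which software, is not given in the sources used here. The trimmed mean, taken after dropping 2% at each end, ranged from 243 to 455 between arrays, a ratio of 1.87, so the deposited intensities had not been scaled to a common brightness. All 8 columns were used. The table has no detection calls, so no statement on background is made, and the number of arrays limits the precision.

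An offset of 10.9 (the 10th percentile of all values) was added to each value, with values below 0 set to 0, before taking log2. Arrays were then quantile normalized, which was the rule fixed for the case that trimmed means differ by more than 5% from their median. Fold changes are on the log2(value + offset) scale and understate the change of dim genes. Quantile normalization assumes that the distribution of signals does not shift between groups. The 64 control probe sets were left out, and probe sets with a mean above the 40th percentile (log2 6.61) were tested, 13575 in all.

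Probe sets were named through the 2016 platform annotation, and symbols were checked by gene number against the mouse RefSeq table of assembly GRCm38.p6, where 20351 of the probe sets with 1 symbol matched. Of 22626 probe sets 20380 had 1 symbol, 691 several and 1555 none. A gene was represented by its brightest tested probe set with 1 symbol, which gave 8352 genes, of which 2823 had 2 or more tested probe sets. Of 392 called genes with several tested probe sets, 307 had all of them in 1 direction, and 1 gene, Ssr4, had probe sets called in opposite directions. Ssr4 was named after its values were seen. Another 128 called probe sets had several symbols or none and were not named.

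Starved was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Camera with a preset correlation of 0.01 compared each of 43 gene lists with the other genes, adjusted over the lists. Of the 16 lists called, 11 held with an estimated correlation. Fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 28 lists. Mean and median, or mean and test, differed in sign for FoxO targets, lipid synthesis, osteoblast and chondrocyte markers, the sarcomere and NF-kappaB targets. Single values were compared with two-sided exact permutation tests over the 70 labellings of 8 arrays.

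Named genes are the 12 highest and the 12 lowest called genes whose arrays do not overlap between groups. For each called list they include the 3 called members with the largest change in its direction and 1 in the other. A fixed panel of 28 genes and up to 3 called members of lists that were not called complete them. The lists, the panel, this rule, the tests and the alternatives were chosen before the data were examined. The exceptions are stated where they appear.

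Alternatives were unscaled values, median or 75th percentile centring, no offset or one at the 25th percentile, and no brightness filter or one at the 60th percentile. Others were eBayes without trend or with robust hyperparameters, array weights, the mean of a gene's probe sets, a 2-fold minimum, and leaving out each array in turn. The members of each called list were also counted without control B, an alternative chosen after the data were seen.

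The procedure was tested on simulated data with 200 of 13575 probe sets changed and another 30 shifted by 0.4 as a list: limma recovered 25.4% of changes of 0.5 on the log2 scale, 78.1% of changes of 1 and 96.4% of changes of 2, and 6 of 129 calls were false. Calls among the 30 were not counted as false. Noise was drawn independently for each probe set, without correlated genes or an outlying array, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.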

Results

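C2C12 cells, a mouse myoblast line that fuses into contractile myotubes when serum is lowered, were differentiated in medium with 2% horse serum and profiled on Affymetrix mouse expression arrays. From day 4 of differentiation the control cultures were re-fed every 48 h, whereas the starved cultures received no fresh medium for 4 days. RNA from both was collected on day 8. There were 4 control arrays (A to D) and 4 starved arrays (E to H). Signals were deposited for 22690 probe sets. The trimmed mean signal was 455, 317, 342 and 423 intensity units in controls A to D and 243, 277, 296 and 366 in starved E to H. The starved arrays were thus dimmer, with a log2 difference of -0.38 that did not pass a two-sided exact permutation test (p = 0.0857, n = 4 per group). Values below are log2 signals after quantile normalization, and errors of the fold changes of genes are standard errors from limma's linear model. Errors of list means are standard errors over the member genes, not over arrays. Adjusted p-values are Benjamini-Hochberg values over all 13575 probe sets tested, and n = 4 arrays per group throughout. The comparison asks which mRNAs differ between myotubes that were re-fed and myotubes left in spent medium, a setting that the labels place under muscle atrophy.

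Starved myotubes raised genes of the ATF4 and amino acid response and lowered genes of the extracellular matrix, of smooth muscle-type contractile proteins and of cholesterol synthesis. Cth, which makes cysteine from cystathionine, rose by 2.89 ± 0.33 on the log2 scale or 7.42-fold (adjusted p = 0.000214). Its control arrays were dim, with a mean intensity of 36.8, so this value depends on the offset. It ran from 2.23 with an offset at the 25th percentile, below gene Trib3 (2.50), to 3.37 without an offset. Other large rises were those of Trib3, a pseudokinase induced by stress (2.72 ± 0.16, 6.61-fold), the secreted hormone Fgf21 (2.57 ± 0.16, 5.92-fold) and Mthfd2 of mitochondrial folate metabolism (2.35 ± 0.11, 5.09-fold). The sulfotransferase gene Chst15 fell by 2.97 ± 0.14 on the log2 scale (adjusted p = 4.78e-07), tenascin C (Tnc) fell by 2.90 ± 0.16, and Tagln, an actin-binding protein of smooth muscle, fell by 2.65 ± 0.15. Chst15 was dim in starved arrays (mean intensity 39.4), and with an offset at the 25th percentile gene Chst15 was at -2.47, a smaller change than that of gene Tnc (-2.59) or gene Tagln (-2.53).

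**Figure D1:**
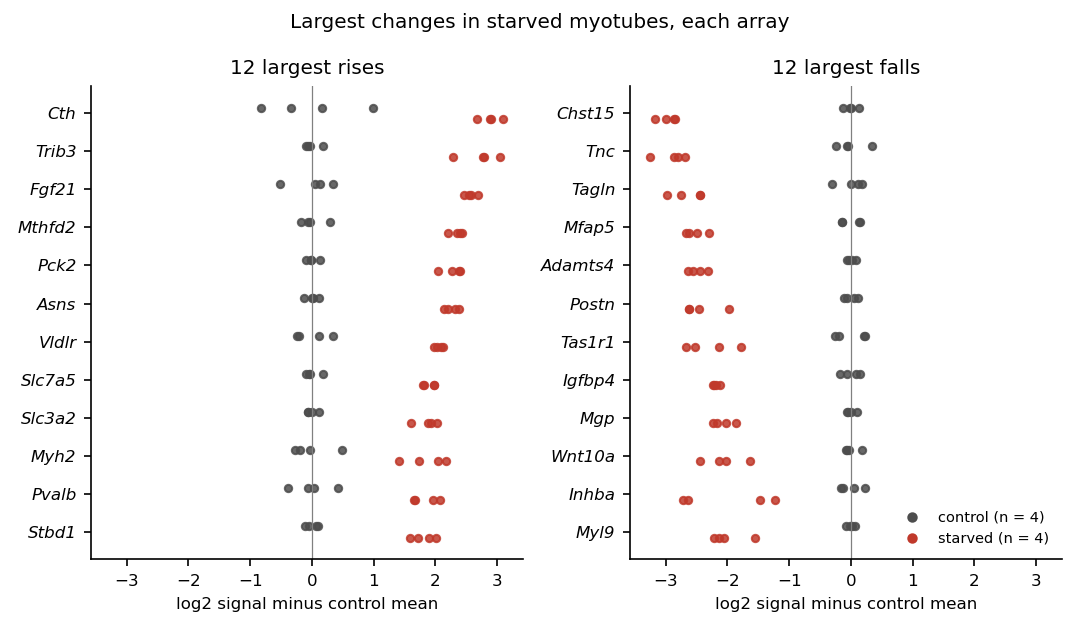
Normalised log2 signal of each array minus the control mean (x axis) for the 12 genes with the largest rise and the 12 with the largest fall among those that passed the test with no overlap between groups; grey points are the 4 control arrays and red points the 4 starved arrays. Starved means lie between 1.80 (Stbd1) and 2.89 (Cth) above the control mean on the left and between -1.99 (Myl9) and -2.97 (Chst15) on the right.

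Of 8352 genes tested through their brightest probe set, 934 passed an adjusted p of 0.05 in limma's test, 355 higher and 579 lower in starved myotubes, so that 38% of the called genes were higher. At least 2-fold changes were seen in 53 of the higher and 116 of the lower genes. The groups did not overlap for 1542 genes, 18.5% of those tested, where chance gives 2.86%. The split between higher and lower rests on the scaling between arrays. With the deposited values left unscaled, 45 genes were higher and 1027 lower (4.2% higher), because the median log2 fold change of all tested probe sets then moved from 0.02 to -0.33. Leaving out starved F lowered the number of higher genes to 226.

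The ATF4 and amino acid response list, fixed before the data were examined, was the most strongly shifted of 43 lists. Of its 33 tested genes 29 rose, 0 fell and 4 did not pass, and 29 also rose when adjusted over the list alone. The mean log2 fold change was 1.33 ± 0.13 (camera, adjusted p = 6.75e-39; 2.05e-04 with the correlation between genes estimated). Among its members Asns, the asparagine synthetase, rose by 2.26 ± 0.08 (adjusted p = 2.20e-07), mitochondrial Pck2 by 2.27 ± 0.11, and Slc7a5 and Slc3a2, the subunits of a leucine transporter, by 1.89 ± 0.08 and 1.86 ± 0.09. Vldlr rose by 2.05 ± 0.14. Atf4 itself rose by 0.67 ± 0.08 (adjusted p = 2.89e-04), the stress transcription factor Ddit3 by 1.44 ± 0.12, Cebpb by 0.47 ± 0.11 and Eif4ebp1, a repressor of cap-dependent translation, by 0.88 ± 0.09. The calls of Atf4, Cebpb and Eif4ebp1 were lost in unscaled values (adjusted p = 0.178, 0.768 and 0.0811). The call of Cebpb was also lost with median centring, without an intensity trend, with the mean of its probe sets, and when control C, starved E or starved H was left out.

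Genes of protein synthesis rose with this response. Aminoacyl-tRNA synthetases, which charge transfer RNAs, had 12 of 18 members higher and 0 lower (14 higher when adjusted over the list alone; mean 0.56 ± 0.07, camera adjusted p = 4.06e-12). Lars rose by 0.95 ± 0.10, Sars by 0.89 ± 0.08 and Nars by 0.88 ± 0.08. In the nucleolus and ribosome assembly list 16 of 39 rose and 0 fell (21 when adjusted over the list alone; mean 0.41 ± 0.05, adjusted p = 5.09e-11). Rrp12 rose by 1.41 ± 0.25, Nop58 by 1.01 ± 0.14 and the transcription factor Myc by 0.91 ± 0.13. Ribosomal proteins rose in 7 of 43 genes (7 when adjusted over the list alone; mean 0.17 ± 0.02, adjusted p = 3.89e-07). That list's call was lost with an estimated correlation (adjusted p = 0.0902), and without control B 11 members were higher. Rps19 rose by 0.57 ± 0.08. Translation factors rose in 8 of 42 genes (10 when adjusted over the list alone; mean 0.15 ± 0.03, adjusted p = 2.64e-04). The largest rise among them was that of the translation repressor Eif4ebp1 (0.88), which is also in the ATF4 list. Eif3c rose by 0.70 ± 0.11 and Eef1b2 by 0.47 ± 0.07. The synthetase list shares the gene Cars with the ATF4 list. The calls of Nars, Nop58, Myc, Rps19, Eif3c and Eef1b2 were lost in unscaled values (adjusted p from 0.0625 to 0.648).

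Chaperone genes were also higher. Heat shock proteins rose in 8 of 33 genes (12 higher and 1 lower when adjusted over the list alone; mean 0.21 ± 0.05, adjusted p = 1.98e-04). The 3 largest changes were in the chaperones Hspe1 (0.97 ± 0.10) and Hspa9 (0.90 ± 0.09), which act in mitochondria, and in Hsph1 (0.65 ± 0.09). Endoplasmic reticulum chaperones rose in 7 of 29 genes (10 when adjusted over the list alone; mean 0.22 ± 0.04, adjusted p = 1.19e-04). Serp1 rose by 0.68 ± 0.15 and Herpud1 by 0.64 ± 0.13. The calls of Hspa9, Hsph1, Serp1 and Herpud1 were lost in unscaled values, where the highest adjusted p was 0.420. In unscaled values the mean of the ribosomal protein list was -0.079, of translation factors -0.21, of heat shock proteins -0.15 and of endoplasmic reticulum chaperones -0.15. Relative to the median of all probe sets in those values they stood 0.25, 0.12, 0.19 and 0.19 higher, and only the call of translation factors was lost (adjusted p = 0.198).

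**Figure D2:**
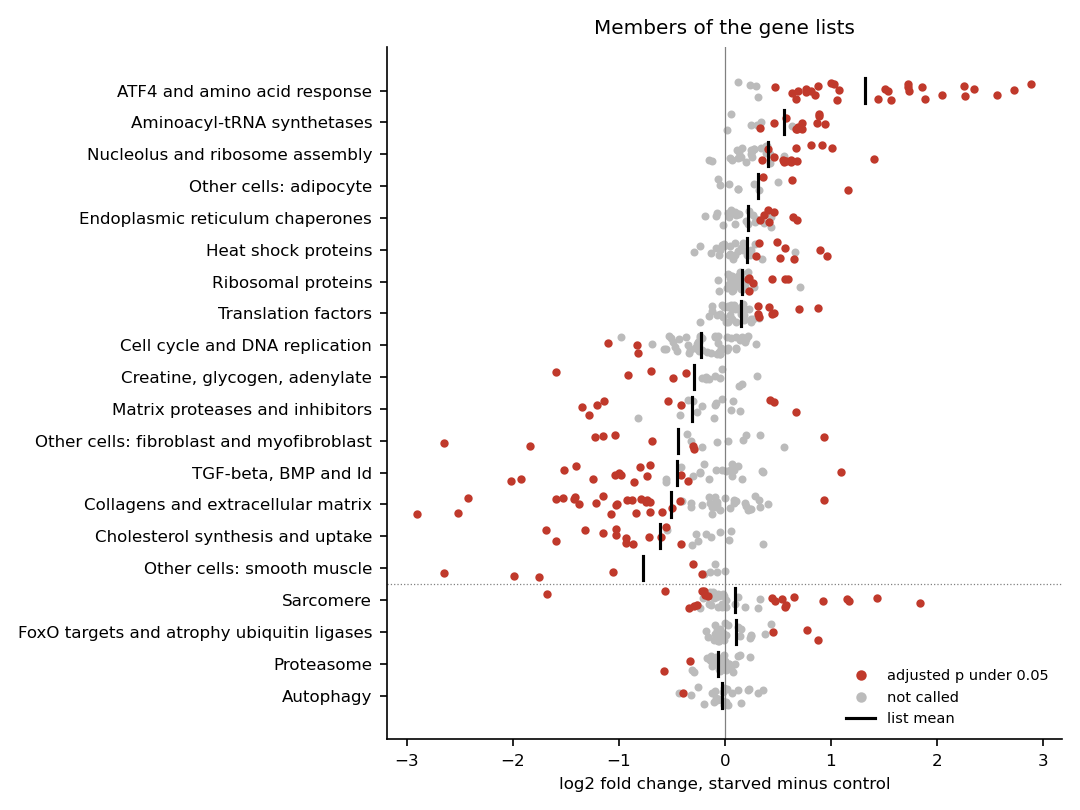
Log2 fold change of each tested gene (starved minus control, x axis) in the 16 gene lists that passed the test and, below the dotted line, in 4 lists that did not; red points passed an adjusted p of 0.05, grey points did not, and the black bar is the list mean. The means run from 1.33 (ATF4 and amino acid response) to -0.77 (smooth muscle markers), and members of the sarcomere list lie on both sides of 0.

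Extracellular matrix genes were lower. Of 53 tested members of the collagen and matrix list 24 fell, 1 rose and 28 did not pass (26 lower and 4 higher when adjusted over the list alone; mean -0.51 ± 0.11, camera adjusted p = 5.81e-11). Besides Tnc, the microfibril gene Mfap5 fell by 2.52 ± 0.13 and periostin (Postn) fell by 2.42 ± 0.15. The other probe set of Mfap5 stood at -0.54 (adjusted p = 0.064), and the mean of both at -1.53. In contrast, the proteoglycan Dcn rose by 0.94 ± 0.14 (adjusted p = 0.00147; 0.0924 in unscaled values). In the TGF-beta, BMP and Id list 14 of 34 members fell and 1 rose (16 and 2 when adjusted over the list alone; mean -0.45 ± 0.12, adjusted p = 8.70e-07). The activin subunit genes Inhba and Inhbb fell by 2.01 ± 0.31 and fell by 1.92 ± 0.09, the matricellular gene Ccn2 fell by 1.52 ± 0.14, and Id3, an inhibitor of basic helix-loop-helix factors, rose by 1.09 ± 0.13. Matrix proteases and their inhibitors had 6 members lower and 3 higher of 22 (the same numbers when adjusted over the list alone; mean -0.31 ± 0.12, adjusted p = 0.0123). That call was lost with an estimated correlation (adjusted p = 0.0695) and with the mean of a gene's probe sets (adjusted p = 0.123). Plat, a plasminogen activator, fell by 1.34 ± 0.22 and the inhibitor Timp1 fell by 1.28 ± 0.10, while Serpinf1 rose by 0.67 ± 0.07 (adjusted p = 0.218 in unscaled values).

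Of the lists for other mesenchymal cell types 3 passed, and that of osteoblasts and chondrocytes did not (0 of 9 higher and 1 lower, also when adjusted over the list alone; mean -0.09 ± 0.28, adjusted p = 0.923). In the smooth muscle list 6 of 11 tested genes fell and 0 rose (6 when adjusted over the list alone; mean -0.77 ± 0.28, adjusted p = 6.74e-07). Beside Tagln, the regulatory light chain Myl9 fell by 1.99 ± 0.14 and the actin Actg2 fell by 1.75 ± 0.17. In the fibroblast and myofibroblast list 8 of 18 fell and 1 rose (10 and 2 when adjusted over the list alone; mean -0.44 ± 0.21, adjusted p = 4.00e-05). Pdgfrb fell by 1.83 ± 0.11 and Cnn2 fell by 1.22 ± 0.09. That list shares 5 tested genes with the matrix list and 2, Acta2 and Tagln, with the smooth muscle list. Adipocyte markers had 3 of 11 genes higher and 0 lower (4 when adjusted over the list alone; mean 0.31 ± 0.11, adjusted p = 0.00886). That call was lost with an estimated correlation (adjusted p = 0.0695). The mean was -0.038 in unscaled values, 0.295 above the median of all probe sets there. The 3 genes were Lpl (1.16 ± 0.15), the glucose transporter Slc2a4 (0.63 ± 0.11) and Dgat2 (0.36 ± 0.10), the first 2 of which muscle cells also use. The call of Slc2a4 was lost in unscaled values (adjusted p = 0.443). The call of Dgat2 was lost in unscaled values, with median centring, with the mean of its probe sets and when any 1 of the 8 arrays was left out.

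Genes of cholesterol synthesis and uptake fell in 13 of 23 tested members and rose in 0 (14 lower and 1 higher when adjusted over the list alone; mean -0.61 ± 0.11, camera adjusted p = 5.81e-11). Cyp51 fell by 1.69 ± 0.09, Idi1 fell by 1.59 ± 0.09 and Msmo1 fell by 1.32 ± 0.11, all enzymes of the pathway (adjusted p from 1.14e-06 to 1.76e-05). In the list of creatine, glycogen and adenylate metabolism 5 of 15 fell (6 when adjusted over the list alone; mean -0.29 ± 0.12, adjusted p = 4.02e-04). The call was lost with an estimated correlation (adjusted p = 0.128). The brain-type creatine kinase Ckb fell by 1.60 ± 0.09 and Adssl1 fell by 0.92 ± 0.13. Glycogen synthase Gys1 fell by 0.69 ± 0.12, although its other probe set stood at 0.78 (adjusted p = 0.62) and the mean of both at 0.043 (adjusted p = 0.965). Cell cycle genes were lower as a list (mean -0.23 ± 0.04, adjusted p = 0.00517), with 3 of 51 members lower and 0 higher, also when adjusted over the list alone. This call was lost with an estimated correlation (adjusted p = 0.167) and with a filter at the 60th percentile of brightness (adjusted p = 0.173). Lig1 fell by 1.10 ± 0.10, Rrm2 fell by 0.83 ± 0.09 and Cdk1 fell by 0.82 ± 0.13.

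Genes of the contractile apparatus changed in both directions. Of 47 tested sarcomere genes 11 rose and 9 fell (13 and 11 when adjusted over the list alone), with a mean of 0.10 ± 0.08 and a median of -0.06, and the list did not pass (adjusted p = 0.923). It passed as higher with median centring or 75th percentile centring, where the lowest adjusted p was 0.0218. Its mean was -0.20 in unscaled values, 0.131 above the median of all probe sets there. Among myosin heavy chains Myh2 rose by 1.84 ± 0.19 (adjusted p = 9.96e-05) and the slow isoform Myh7 by 1.44 ± 0.09 (adjusted p = 1.75e-06), while the fast isoform Myh4 fell by 1.67 ± 0.19 (adjusted p = 1.68e-04). These 3 directions held in each scaling. Perinatal Myh8 and Myh1 lie outside the rule for named genes and were added after their values were seen: Myh8 rose by 1.16 ± 0.08. Myh1 was at -0.19 ± 0.05 (adjusted p = 0.0218), a call lost in each other scaling (adjusted p from 0.0535 to 0.903), and its other probe set stood at 0.14 (adjusted p = 0.394). Embryonic Myh3 (-0.13 ± 0.05, adjusted p = 0.109), skeletal actin Acta1 (-0.01 ± 0.05, adjusted p = 0.950) and muscle creatine kinase Ckm (-0.22 ± 0.09, adjusted p = 0.166) did not pass. Ckm was called lower in unscaled values (-0.58, adjusted p = 0.00921). The myogenic factors Myog (0.29 ± 0.14, adjusted p = 0.238) and Myod1 (0.36 ± 0.11, adjusted p = 0.0600) did not pass either. Myod1 was called higher with 75th percentile centring, with a filter at the 60th percentile and without starved G (lowest adjusted p = 0.0253). The groups did not overlap for Myh3, Myog and Myod1. In the list of myogenic regulators 0 of 13 genes rose and 2 fell (1 and 3 when adjusted over the list alone; mean -0.12, adjusted p = 0.120). Mef2c fell by 0.33 ± 0.05, a call lost with median centring, while its other 4 probe sets were all called lower and the mean of all was -0.76. Mef2d fell by 0.56 ± 0.10, a call lost with the mean of its probe sets (adjusted p = 0.116). Pvalb, a calcium buffer of fast fibres, rose by 1.84 ± 0.17, and Stbd1, a glycogen-binding protein, by 1.80 ± 0.11.

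**Figure D3:**
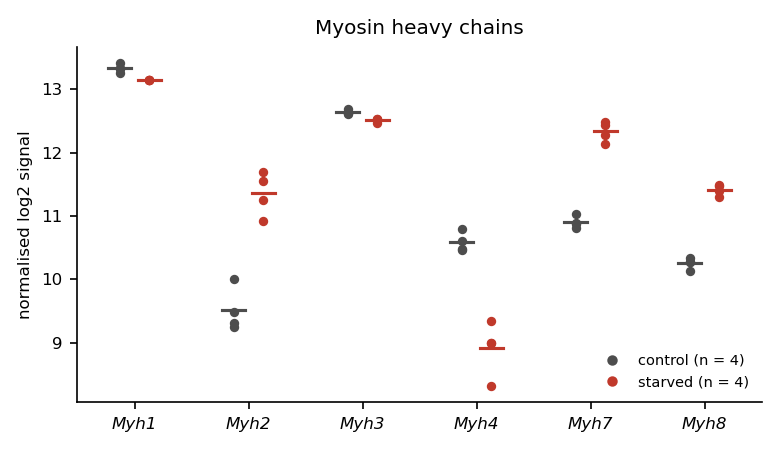
Normalised log2 signal (y axis) of 6 myosin heavy chain genes in each of 4 control (grey) and 4 starved (red) arrays, with bars at group means. Myh2, Myh7 and Myh8 are higher in starved arrays by 1.84, 1.44 and 1.16 and Myh4 differs by -1.67, while Myh1 (-0.19 on the brighter of its 2 probe sets) and Myh3 (-0.13) lie within 0.2 of the control mean.

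Genes of protein breakdown moved little as groups compared with other genes. In the list of FoxO targets and atrophy ubiquitin ligases 3 of 29 genes rose and 0 fell (4 when adjusted over the list alone), with a mean of 0.10 ± 0.05, a median below 0 (-0.004) and a camera adjusted p of 0.240. The 3 were Eif4ebp1, Txnip (0.77 ± 0.12, adjusted p = 0.00212; 0.25 in unscaled values) and Fbxo32, the muscle ubiquitin ligase also called atrogin-1, which rose by 0.45 ± 0.13 (adjusted p = 0.0460). The call of Fbxo32 was lost in each other scaling, without a brightness filter, without an intensity trend, with the mean of its probe sets and when any 1 of controls A, C and D or starved E, F and G was left out, with log2 fold changes from 0.09 to 0.52 over all alternatives. The proteasome had 2 of 34 genes lower and 0 higher (mean -0.06 ± 0.03, adjusted p = 0.225), with the same numbers when adjusted over the list alone, and it passed as lower in unscaled values (adjusted p = 0.0125). Autophagy genes had 1 of 25 lower (0 when adjusted over the list alone; mean -0.03 ± 0.04, adjusted p = 0.923), and lysosomal genes 6 lower and 2 higher of 41 (the same when adjusted over the list alone; mean -0.05 ± 0.04, adjusted p = 0.322). Ubiquitin conjugation had 2 higher and 2 lower of 30 (mean -0.09 ± 0.04, camera adjusted p = 0.225). Calpains and caspases had 1 higher and 3 lower of 24 (mean -0.10 ± 0.07, camera adjusted p = 0.28). With fry the lists of FoxO targets, lysosome, ubiquitin conjugation, and calpains and caspases passed (adjusted p from 0.0048 to 0.028). Of these lists only FoxO targets had a mean above 0. The proteasome and autophagy lists did not pass with fry. Foxo1 (-0.18 ± 0.12), Foxo3 (-0.10 ± 0.14), Bnip3 (-0.09 ± 0.11), Ctsl (0.12 ± 0.08), Cdkn1a (-0.09 ± 0.06) and Igf1r (-0.26 ± 0.14) did not pass. Igfbp5 rose by 0.47 ± 0.07 and the metallothionein Mt2 by 0.42 ± 0.08, both lost in unscaled values (adjusted p = 0.325 and 0.819), and Mt2 also with median centring. Mt1 (0.15 ± 0.12), Fos (0.13 ± 0.40) and Junb (-0.05 ± 0.20) did not pass. Bcl3 and Irs2 were too dim to be tested, Gapdh was only on control probe sets, which were left out, and on probe sets that match several genes, and Mstn, Nfkb1 and Trim63 had no probe set with a single gene symbol in the annotation used here.

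Array quality differed in 1 control. Control B had a 3' to 5' log2 ratio of 1.40 for its Gapdh control probe sets, against -0.22 to -0.12 in the other 3 controls and -0.23 to -0.04 in the starved arrays. It was separated from the other 7 arrays on the second principal component, which held 19.1% of the variance. The first component (36.8%) separated the groups. For Tfrc the ratio was higher in starved arrays (1.92 ± 0.56, SD, n = 4) than in controls (0.76 ± 0.17, SD, n = 4). The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. The Benjamini-Hochberg adjusted p was 0.143 over the 5 control transcripts. The Tfrc 5' signal was dim, at a normalised log2 of 5.5 to 5.9 in controls and 4.4 to 5.2 in starved arrays. Both ranges lie below the brightness filter used for the tested probe sets. A group difference in RNA quality therefore cannot be read from the Tfrc ratio. The 3' to 5' ratios were not computed from the quantile normalized signals. Without control B 370 genes were higher and 526 lower, and 789 of the 934 called genes were still called in the same direction. In the matrix list without control B 25 genes were lower and 2 higher.

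**Figure D4:**
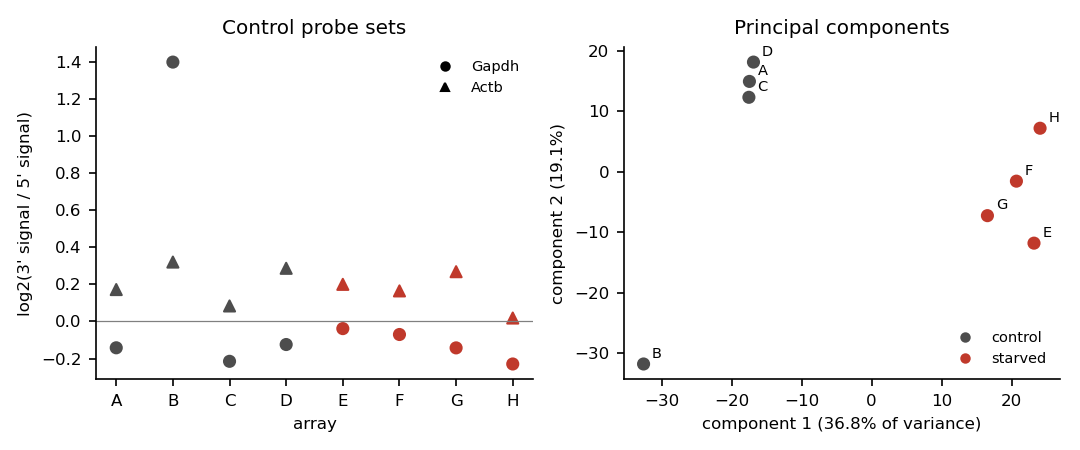
Left, log2 ratio of 3' to 5' signal of the Gapdh (circles) and Actb (triangles) control probe sets on each array; right, the arrays on the first 2 principal components of the normalised log2 signals, with controls in grey and starved arrays in red. Control B has a Gapdh ratio of 1.40 and lies at -31.8 on component 2.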

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

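The test of 3' to 5' ratios in control B, the test of its label, the distance between myosin heavy chains and the test of actin genes without shared genes were chosen only after those results were seen, and the statement that the myosin distance tests was narrowed after its value was known. The tests of fibre genes, fibroblast markers and actin genes were written to explain changes already seen. Their bounds were set before their own values were known. Among 376 sets of 4 arrays of a group, 21 held 1 array far from the other 3, where chance gives about 1 in 20, or 18.8. Of these 7 were in control B.

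Control B was the far array for the normalised log2 signals of Acta1 (13.4544, where the other 3 controls are tied at 13.5348 by the normalization), Cdk1 (7.9733), Elovl5 (8.8892), Myog (11.9002) and Nes (12.3438), for the Gapdh 3' to 5' log2 ratio (1.3992) and for the mean of the TGF-beta, BMP and Id list (8.9978). Partly degraded RNA or shortened cDNA in control B predicted the highest 3' to 5' ratio of the controls for at least 4 of 5 control transcripts, and 4 were highest there. Gapdh, 1 of the 4, had prompted the test. The ratio of 18S rRNA was higher (3.39, against at most 2.69), but it rests on a dim 5' signal. In normalised log2 signal the 18S 5' probe set was at 4.54 in control B, against 7.36 to 9.35 in the other controls. The 18S 3' probe set was lowest there too (8.09, against 9.54 to 12.14). The margins were slight for Actb (0.32 against 0.29) and Pcx (2.29 against 2.16). Control B was lowest for Tfrc (0.53), a ratio that also rests on a dim 5' signal. A starved culture under a control label is argued against, because the mean of the ATF4 list placed control B at 0.0153 on a scale from 0 at the other controls to 1 at the starved arrays, with a spread of 0.0383. Lower RNA integrity in this 1 array stays open as a hypothesis found on these data, which the count does not settle. No biological explanation was tested.

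Single arrays stood apart in other results. Control C was low for Cyp51 (9.8566), control D for the mean of the calpain and caspase list (8.6001) and control A for that of the hypoxia list (8.9628). Starved E was low for Fos (5.634) and high for the Pcx 3' to 5' log2 ratio (2.4281) and the mean of the lysosome list (9.8814). Starved F was low for Ckb (9.2412). Starved G was low for Ckm (11.9298), Ephx1 (9.5181) and the mean of the fatty acid oxidation list (9.3519), and high for Psmd10 (8.0515) and Slc2a4 (8.6598). Starved H was low for Cp (9.3967) and high for Ctsl (12.3924).

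Myh2 and Myh7 rose while Myh4 fell, and probe sets of such similar genes could read each other's transcripts. If all of them read 1 shared signal their fold changes would lie within 1 of each other on the log2 scale. Myh2 and Myh4 were 3.52 apart (SE 0.267), but this distance restates the rise and fall that prompted the question and adds no separate evidence. The opposite directions themselves are not what 1 signal shared by all would give. It stays open that Myh2, Myh7 and Myh8, which rose together, share signal in part, since probe sequences were not used here. A general rise of slow over fast fibre genes predicted a difference above 0.3 without the myosin heavy chains; it was 0.274 (two-sided exact permutation p = 0.0286, the smallest possible), between the bounds set in advance, so it cannot be told apart from a smaller shift. The medians of the lists differed less, at -0.057 for slow and -0.14 for fast genes, so that the mean difference rests on the 4 slow genes that rose. Of these Ankrd2 (1.17) and Tpm3 (0.65) rose most, while Atp2a2 (-0.23) and Tnnt1 (-0.16) were lower, and Ckm of the fast list had been seen when the test was written. Pvalb, a calcium buffer of fast fibres that rose by 1.84, is not in the fast list and goes against a rise of slow over fast genes. All 13 slow and 15 fast genes are also in lists reported above, so the test is not independent of those.

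Tnc, Postn, Tagln and other matrix and contractile genes fell. Loss of fibroblast-like cells predicted that their surface and transcription factor markers fell as far as the 24 matrix genes that fell (median -1.02). The markers had a median log2 fold change of 0.176 (SE 0.251 over the member genes, not over arrays). Their mean was of the other sign, at -0.076. As a set they did not fall as far as those genes. However, the 24 were picked by their fall, and the median of all 53 tested matrix genes was -0.32. The comparison therefore does not decide whether a smaller loss of such cells took part. Pdgfrb, which had been seen, was the 1 marker that passed (-1.83), and 7 of the 11 markers are also in a list above. Lower activity of serum response factor predicted a fall of actin cytoskeleton genes, and their mean log2 signal differed by -0.426 (two-sided exact permutation p = 0.0286). Their mean was -0.782 in unscaled values, -0.462 with median centring and -0.422 with 75th percentile centring. Relative to the median of all tested probe sets it was -0.444 after quantile normalization. In the other scalings it was -0.449, the same value by construction, since they differ by a constant per array. The median log2 fold change of the actin genes was smaller, at -0.265, with 8 of 19 called lower and 0 higher. Cnn2 (-1.22) had been seen when this test was written, and 5 of the 19 genes are also in lists above. Without these 5 the difference was -0.312 (two-sided exact permutation p = 0.0286). Lower activity stays open as a hypothesis, but mRNA levels of targets do not measure the factor. The fixed list of genes that respond early to serum did not pass (6 higher and 11 lower of 33, camera adjusted p = 0.134). Whether loss of other serum signals caused the fall was not tested.

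In the real split 1437 probe sets were called, against at most 1 in the other splits of the 8 arrays into 4 and 4. Genes called higher were 355 against 0 and genes called lower 579 against 0. For each of these counts 1 of 35 splits, the real one, gave as many. That is the smallest share possible, so chance is made less likely but not excluded. The other splits also mix both groups, so a group difference widens the spread within their sides and lowers their counts. If the replicates were technical, a difference between single cultures would look the same. For the number of gene lists the real split did not stand out (16 against 17 in another split), and 3 of 35 splits gave as many. In the 18 splits with 2 controls on each side at most 1 list was called, and in the 16 that exchange 1 array per group 7 to 17 were.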

How the results depend on the processing

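The count of members of each called list without control B was chosen only after the data were seen. Of 125 called named genes 66 kept direction and call in every alternative and 25 were lost only in unscaled values. Of 16 called lists 8 kept both. The cause of the changes below was not tested, except that unscaled values lower the median of all tested probe sets to -0.33. In unscaled values genes higher in starved were 45 and genes lower in starved 1027. There the list means turned to -0.26 (FoxO targets), -0.20 (sarcomere), -0.34 (tricarboxylic acid cycle), -0.29 (oxidative phosphorylation) and -0.30 (fatty acid oxidation). They were -0.15 for endoplasmic reticulum chaperones and for heat shock proteins, -0.079 for ribosomal proteins, -0.21 for translation factors and -0.27 for p53 targets and for complement. Markers of undifferentiated myoblasts were at -0.20, of adipocytes at -0.038 and of macrophages at -0.24. Ctsl was at -0.22, Fos at -0.18, Mt1 at -0.20 and Stub1 at -0.022. With median centring 219 genes were higher in starved, Acta1 was at 0.081, Cdkn1a at 0.028 and the tricarboxylic acid cycle at -0.017. With 75th percentile centring Acta1 was at 0.12, Cdkn1a at 0.067 and list NF-kappaB targets and chemokines at 0.0084. That list was at 0.0044 with an offset at the 25th percentile and at 0.21 without a brightness filter. It was at 0.028 with a filter at the 60th percentile, at 0.032 with array weights and at 0.028 with the mean of a gene's probe sets. Without a filter list Tricarboxylic acid cycle was at -0.0032. At the 60th percentile hypoxia was at 0.049 and lipid synthesis at 0.042. Gys1 was at 0.043 with the mean of its probe sets. With a 2-fold minimum the number of probe sets called was 273, with 53 genes higher and 116 lower, by construction.

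Leaving out 1 array at a time gave 226 to 370 genes higher, 436 to 541 lower and 1061 to 1444 probe sets called. Log2 fold changes over these fits ran from -0.032 to 0.013 for gene Acta1, from -0.065 to 0.62 for gene Fos and from -0.29 to 0.052 for gene Junb. They ran from -0.040 to 0.010 for list Fatty acid and lipid synthesis and from -0.015 to 0.035 for list NF-kappaB targets and chemokines. The number of control transcripts with an exact p under 0.05 for the 3' to 5' signal of control probe sets went from 1 to between 0 and 2. For Tfrc the exact p was 0.0571 with any 1 control left out and 0.0286 with any 1 starved array left out. The 3' to 5' difference of Gapdh ran from -0.50 to 0.040, the latter without control B. Without control B list Oxidative phosphorylation passed as higher (mean 0.088), as it did without starved F (0.072), and list Muscle membrane and excitation-contraction coupling passed as lower (mean -0.11).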

Other observations

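No test reported in this part was chosen after its result was seen. The list of IGF and insulin signalling did not pass (camera adjusted p = 0.282). In it Igf2 rose by 1.67 ± 0.09 on the log2 scale, a 3.19-fold change (limma, adjusted p = 5.67e-07), while the binding protein genes Igfbp4 and Igfbp7 fell by 2.19 ± 0.09 and fell by 1.47 ± 0.09 (n = 4 arrays per group). In all 3 of its 27 tested genes rose and 5 fell (4 and 6 when adjusted over the list alone). Genes that respond early to serum had 6 members higher and 11 lower of 33, with the same numbers when adjusted over the list alone (adjusted p = 0.134). Of these Egr2 fell by 1.25 ± 0.19. In the Notch list 1 gene rose and 4 fell of 21 (1 and 5 when adjusted over the list alone; adjusted p = 0.270), with Hes1 and Hes6 at -0.70 ± 0.12 and -0.69 ± 0.09 and the receptor Notch1 at 0.53 ± 0.12, the last lost in unscaled values (adjusted p = 0.602).

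Stress genes outside the ATF4 list were mixed. Heme oxygenase Hmox1 rose by 1.13 ± 0.22 (adjusted p = 0.00728; 0.0690 in unscaled values) and Ephx1 by 1.05 ± 0.10, while thioredoxin Txn1 fell by 0.73 ± 0.06, a call lost with the mean of its probe sets (adjusted p = 0.201). The oxidative stress list had 4 of 38 genes higher and 4 lower (5 and 4 when adjusted over the list alone; adjusted p = 0.465). Sesn2, a stress-induced inhibitor of TORC1 signalling that is itself a member of the ATF4 list, rose by 1.57 ± 0.19. Tas1r1, a taste receptor gene that takes part in sensing amino acids, was among the 12 lowest genes and fell by 2.28 ± 0.22 (adjusted p = 6.60e-05), to a mean intensity of 48.3 in the starved arrays from 333 in the controls. Markers of endothelium (0 of 11 called, adjusted p = 0.977) and of macrophages and leukocytes (0 of 7, adjusted p = 0.660) did not pass the test.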
